A study of Mus musculus with 18 samples.

How the data were processed

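The series holds 18 libraries of T cells from mouse spleen, sorted by flow cytometry and kept for 72 h on plate-bound anti-CD3 (2 µg/ml) with anti-CD28 (2 µg/ml) and IL-2 (10 ng/ml). The labels name CD8, CD4 and Treg cells of Foxp3 YFP/cre mice, here called WT, and of Foxp3 YFP/cre mice lacking Ebi3, here called KO, with 3 libraries of each. Per the labels' protocols, 500 ng of total RNA went into each QuantSeq 3' FWD library, which reads the 3' end of polyadenylated RNA, with unique molecular identifiers added. The labels do not say whether the CD4 cells were sorted as Foxp3-negative, whether the same animals gave all cell types, or whether replicates were separate animals or cultures.

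The deposited values are raw counts per Ensembl gene, 55487 genes by 18 libraries, not normalised. Per the submitters' processing notes, FastQC, cutadapt 2.10, STAR 2.5.3a, UMI-tools 1.0.0, featureCounts and Subread 2.0.0 were used with GRCm38 (mm10). These notes give no order or settings, so the annotation release, the treatment of reads with several alignments and the strand setting of the counting are not given in the sources used here. Near-identical genes such as Hba-a1 and Hba-a2, genes with processed pseudogenes such as Gapdh, and genes that overlap on either strand are therefore uncertain. A 3' tag counts each transcript near its end only, and says nothing about exons further upstream. Gene names and positions came from an annotation of GRCm38 with 55536 genes, of which 55227 of the genes in the table matched, and 346 genes had no symbol. All columns of the table belong to a labelled library, and 0 columns were left unused.

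Total counts summed to 28653307, from 841892 to 2255950 per library, and 30423 genes had any count. At this depth a floor of 3 counts in a library corresponds to 1.33 to 3.56 CPM, and all intervals (95%, exact, on counts) and floors cover counting error only. The common dispersion of the fit was 0.00977.

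Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 (12693 genes), scaled by TMM and fitted with glmQLFit (robust) on the means of the 6 groups over all 18 libraries (12 residual degrees of freedom), so that the groups share 1 estimate of the spread. Contrasts were tested with glmQLFTest and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Comparisons were KO against WT in CD8, CD4 and Treg and averaged over the 3 cell types, the differences of that effect between cell types, and CD8 against CD4 and Treg against CD4 in WT. With 3 libraries against 3 an exact permutation test of a single value cannot go below 0.1, so moderated tests across genes were used. Normalised values are CPM of the TMM-scaled library size. A replicate pair was counted as 1 sample in means where a chi-square test over genes with at least 20 summed counts found no difference within the group, which was so for 2 Treg pairs.

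Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and lists of at least 5 tested genes (30 of 31 lists), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The 31 lists, all fixed before the data were examined from textbook knowledge, cover EBI3 cytokine subunits and receptors, interferon-stimulated genes, STAT3 and IL-27 response, IL-2 and STAT5 response, inhibitory receptors, cytotoxic genes, Th1, Th2, Th17, follicular helper, Treg, naive and memory, T cell activation, NF-kappaB response, S phase, G2 and M phase, glycolysis and hypoxia, oxidative phosphorylation, sterol and fatty acid synthesis, amino acid stress and unfolded protein, p53 and apoptosis, chemokine receptors, cytokines, CD8 lineage, CD4 lineage, stress and immediate early genes, sex-linked genes, and markers of B cells, myeloid and dendritic cells, NK and innate-like T cells, and erythroid cells and platelets. Some genes stand in several lists, Slc7a5 among T cell activation and amino acid stress genes for example. List tests were not run for the comparisons between cell types, where members are counted.

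The design, the tests, the lists, the first set of alternatives and the rule for named genes were set before the data were examined. By that rule the text always gives Ebi3, Cd8a, Cd8b1, Cd4, Zbtb7b and Foxp3. For each comparison it names, among genes past the threshold with a mean log2 CPM of 2 or more and groups entirely apart, the 10 largest rises and 10 largest falls (5 and 5 for differences between effects and between cell types), passing over predicted genes, and up to 4 members of each list past the threshold or, for a list that passes, of largest fold change. Genes past the threshold over the list alone, genes behind a count of 5 or fewer under an alternative, Hjurp, Ide and the other genes called with a covariate, and all genes named in the last part were chosen after their values were seen. Some of the genes picked in these ways are not reported here, and the counts still include them.

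The edgeR test was run on simulated counts drawn from the means and sizes of the real libraries, except for the differences Treg minus CD4 and Treg minus CD8. The list tests were run so for KO against WT in CD8 only. Of genes changed 1.5-, 2- and 4-fold, 19.4%, 64.2% and 89.4% were recovered for KO against WT in CD8 (12419 genes, 10 false calls), 29.9%, 73.1% and 87.9% in CD4 (12449 genes, 12 false calls), 14.9%, 52.2% and 77.3% in Treg (12452 genes, 3 false calls), 64.2%, 86.6% and 97% for the average (12399 genes, 6 false calls), 4.48%, 34.3% and 81.8% for CD4 minus CD8 (12430 genes, 5 false calls), 32.8%, 58.2% and 90.9% for CD8 against CD4 (11514 genes, 13 false calls) and 26.9%, 50.7% and 80.3% for Treg against CD4 (11544 genes, 5 false calls). When the 30 G2 and M phase genes were shifted 1.25-fold in CD8, camera returned that list (adjusted p = 2e-15, and 1.87e-05 with an estimated correlation) and 0 other lists. Simulated genes were drawn independently of each other, whereas the estimated correlation of this list in the real CD8 comparison was 0.41. The run therefore says nothing about false calls of camera with the preset correlation where list members move together. Each simulated gene also had the same spread in all groups, without the real differences in hemoglobin between libraries. The shares recovered may therefore not hold for the real libraries.

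Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0 (which replaced its parametric dispersion trend by a local fit), limma-voom, a fold change over 1.5 in the test (glmTreat), the replicate number as a block, the number within a genotype as a block, a fit of only the libraries compared, sums of same-numbered libraries for the average, and each library left out in turn. A hemoglobin covariate (log2 of Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 in CPM, centred within the cell type), a fit of the 12 CD4 and CD8 libraries, the mean over CD4 and CD8 only, sums of Treg libraries that differed by less than the sampling noise, and list tests without each library were added after the data had been seen. Splits of the libraries into other groups numbered 10 for 3 against 3 and 100 random ones (seed 1) otherwise. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.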

Results

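Messenger RNA was counted in T cells sorted from mouse spleen and stimulated in culture for 72 h through CD3 and CD28 in the presence of IL-2. The mice carried YFP/cre in Foxp3, the gene of the transcription factor that defines regulatory T cells (Treg), and were labelled wild type (WT) or knockout (KO) for Ebi3. Ebi3 encodes a subunit shared by the cytokines IL-27 and IL-35. The labels give 18 libraries in 6 groups, 3 libraries for each genotype of CD8, CD4 and Treg cells. Total counts per library ranged from 1358671 to 2255950 in the CD4 and CD8 groups and were lowest, at 841892, in Treg WT replicate 1. Counts came from 3' tags with unique molecular identifiers, and intervals and floors below cover counting error only. No source used here states whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples. Treg WT replicates 1 and 2 differed by less than the sampling noise (chi-square per gene 0.923), as did Treg KO replicates 1 and 3 (0.914). Each of these pairs was counted as 1 sample in the Treg means, which leaves n = 2 per genotype. Of 9 Treg pairs across the genotype labels 4 also showed no difference beyond sampling noise, and these stayed separate samples. The Treg samples of WT and KO may therefore not be independent of each other. Within-group pairs of CD4 and CD8 libraries differed by 1.502 to 5.301 on the same scale.

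The targeted gene, Ebi3 (ENSMUSG00000003206, chromosome 17, 55952640 to 55957022 in GRCm38), was counted in every library, those labelled KO included. In CD4 cells its normalised level was 46.2 ± 12.4 CPM (SD, n = 3) in WT and 23 ± 2.84 CPM (SD, n = 3) in the libraries labelled KO. In CD8 cells the levels were 28.9 ± 0.845 and 28.6 ± 4.97 CPM (SD, n = 3 each), and in the libraries labelled Treg 35.3 ± 6.89 and 30.7 ± 5.38 CPM (SD, n = 2 each). Single CD8 libraries gave 29.1, 28 and 29.7 CPM in WT and 27.6, 24.2 and 34 in KO. Single CD4 libraries gave 60.5, 38.7 and 39.4 CPM in WT and 20.6, 26.1 and 22.5 in KO. Single Treg libraries gave 35, 25.8 and 40.1 CPM in WT and 29.2, 34.5 and 24.6 in KO. The log2 fold change of KO against WT was -0.98 (SE 0.19) in CD4. Ebi3 had the lowest p of all genes there (edgeR quasi-likelihood test, unadjusted p = 9.98e-06). It still missed the threshold over all genes (adjusted p = 0.127). The adjustment covers all genes tested, whereas Ebi3 was set to be reported before the data were examined. Its log2 fold change was -0.01 (SE 0.19, unadjusted p = 0.954, adjusted p = 1 by edgeR) in CD8. In Treg it was -0.20 (SE 0.24, unadjusted p = 0.428, adjusted p = 0.999 by edgeR). The deleted part of the gene and the place of any reporter are not given in the sources used here. A 3' tag may lie outside the deleted part, and then checks nothing about the genotype labels. Because Ebi3 did not separate the CD8 or the Treg libraries by label, KO and WT below mean the libraries so labelled, and Treg is likewise used only as the label of 6 libraries.

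Ebi3 was also set against hemoglobin transcripts (Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2), which belong to red cell precursors and were counted in every library. In CD8, Ebi3 per 1000 hemoglobin counts stood at 46.6, 39.7 and 28.5 in WT and at 25.8, 24.7 and 23.2 in KO. In CD4 it stood at 40.4, 45.7 and 37.6 in WT and at 27.6, 26.5 and 25.6 in KO. All 6 libraries labelled KO lay below all WT libraries of their cell type, with a mean log2 difference of -0.62. A two-sided exact permutation test within cell types gave p = 0.005 over 400 arrangements (adjusted p = 0.0125 over 5 relations, computed after the levels had been seen). In CD8 the log2 difference of Ebi3 in CPM was -0.05 and that of hemoglobin 0.57, so that the ratio was lower there because its denominator was higher. Per count of T cell receptor and CD3 genes (Trac, Trbc1, Trbc2, Cd3d, Cd3e and Cd3g) the log2 difference of Ebi3 was 0.36 in CD8 and -1.26 in CD4 (exact permutation p = 0.275, adjusted p = 0.344), and 3 of the 6 libraries labelled KO, those of CD4, lay below all WT libraries of their cell type. For Ebi3 in CPM the log2 difference over the same 12 libraries was -0.51 (exact permutation p = 0.035, adjusted p = 0.0583). In the CD4 libraries Ebi3 followed hemoglobin with Pearson's r = 0.88 (n = 6, exact permutation p = 0.0222, adjusted p = 0.0315 over 12 relations). Spearman's rho was 0.66 (exact permutation p = 0.175, adjusted p = 0.233), and r was 0.23 without the 2 farthest libraries, so that the relation rests on those. In the CD8 libraries r was 0.5 (n = 6, exact permutation p = 0.285, adjusted p = 0.336) and 0.01 without the 2 farthest. Spearman's rho was 0.31 there (exact permutation p = 0.564, adjusted p = 0.615).

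**Figure D1:**
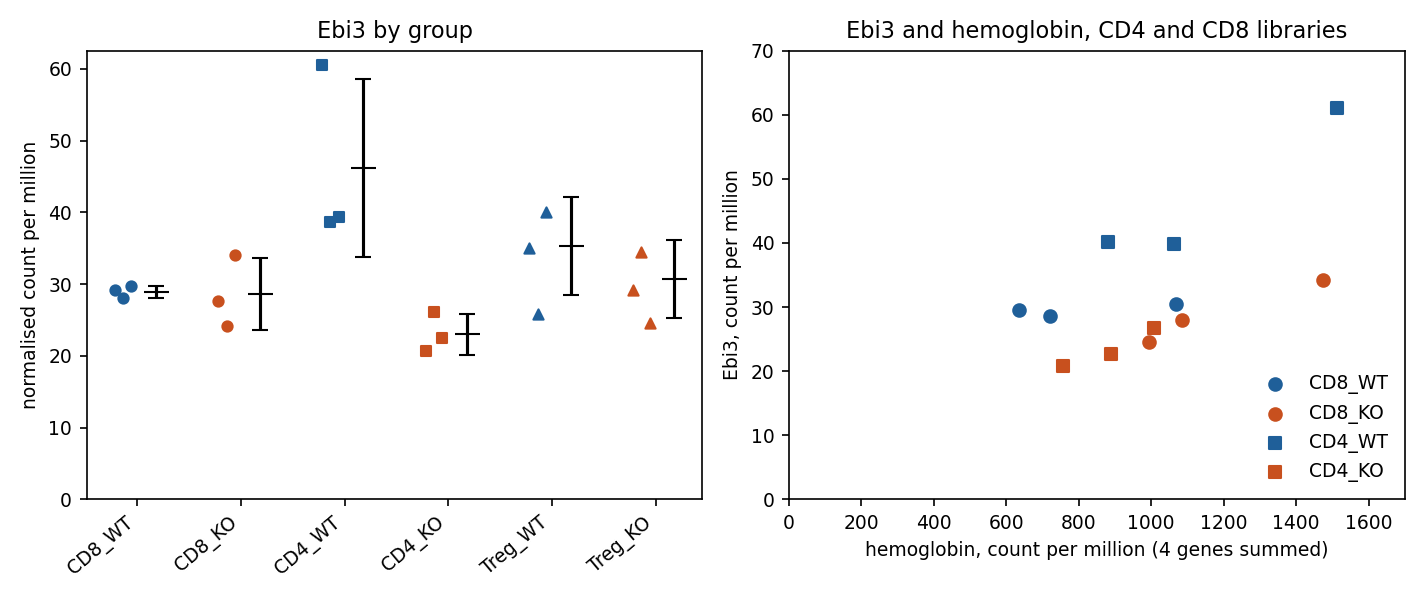
Left, normalised Ebi3 level (CPM) in each library by group, with the mean and SD of each group (n = 3, and n = 2 in the Treg groups, where pairs within sampling noise count as 1). Right, Ebi3 against hemoglobin (both CPM) in the 12 CD4 and CD8 libraries; CD4 WT replicate 1 has the highest Ebi3 level, 60.5 CPM when normalised.

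The lineage genes followed the CD4 and CD8 labels and set the libraries labelled Treg apart. Cd8a and Cd8b1, which encode the CD8 coreceptor, reached 143 to 244 and 128 to 192 CPM in the CD8 libraries, against 0 to 1.69 and 1.46 to 11.7 CPM in the CD4 libraries. Cd4 stood at 100 to 157 CPM in the CD4 libraries and at 0 to 0.509 CPM in the CD8 libraries. Zbtb7b, the factor that directs CD4 commitment in the thymus, was at 41.6 to 55.1 CPM in CD4 and 29.9 to 43.3 CPM in CD8. The Treg libraries held both coreceptors, with Cd8a at 24.9 to 46.7, Cd8b1 at 33.5 to 47.9, Cd4 at 34.4 to 68 and Zbtb7b at 52.6 to 72.5 CPM. Foxp3 had 0 or 1 count in each of the 18 libraries, Treg included. All mice carried YFP/cre in Foxp3, and whether this changes the 3' tag of the gene was not tested. Its level was not detectable at this depth, where 3 counts correspond to between 1.33 and 3.56 CPM. The first principal component of the 18 libraries, with 69.3% of the variance, placed all Treg libraries at 69.1 to 82 and all others at -47.4 to -24.9.

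**Figure D2:**
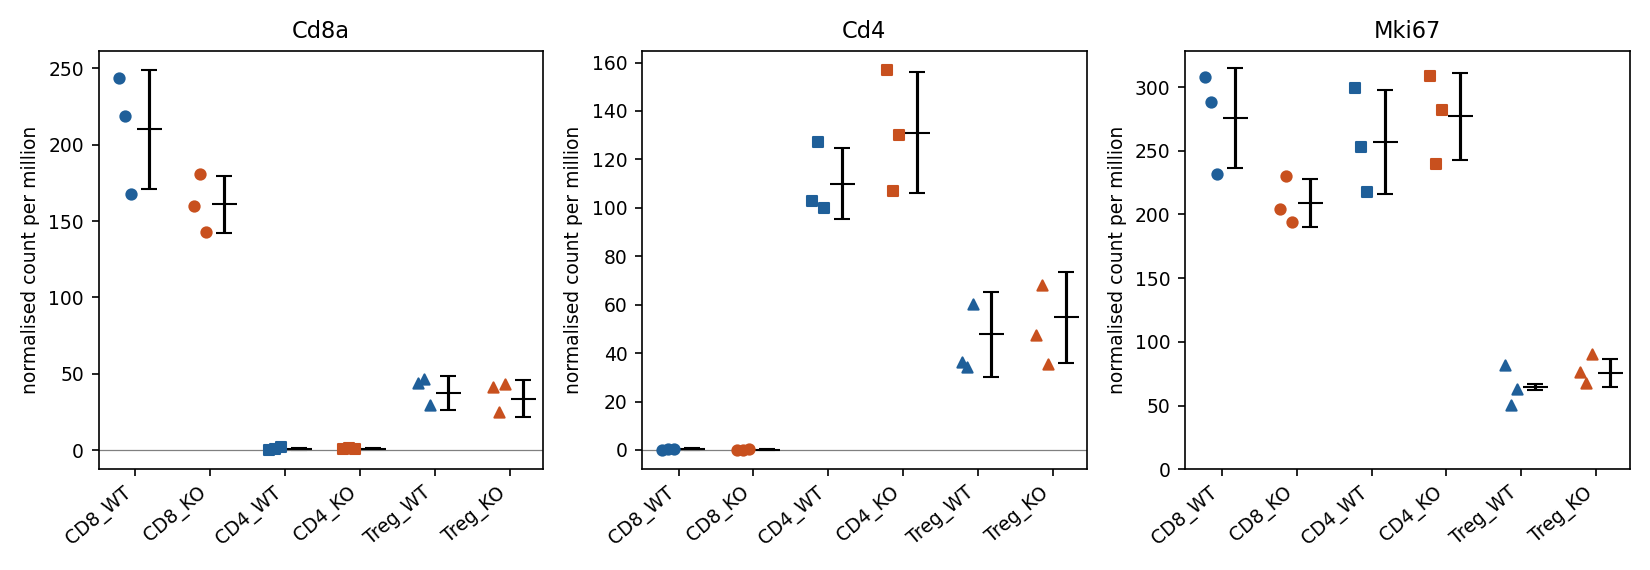
Normalised level (CPM) of Cd8a, Cd4 and the proliferation gene Mki67 in each library by group, with the mean and SD of each group (n = 3, and n = 2 in the Treg groups). The Treg libraries sit between the CD8 and CD4 libraries for both coreceptor genes, Cd8a at 24.9 to 46.7 CPM and Cd4 at 34.4 to 68 CPM.

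In CD8 cells, 7 genes were higher and 14 lower in the libraries labelled KO than in WT. The largest named fall was that of Bola1, whose product helps maintain mitochondrial iron-sulfur proteins (ENSMUSG00000015943, chromosome 3, 96196588 to 96219709). It went from 51.9 ± 9.93 to 26.6 ± 3.70 CPM (SD, n = 3 each), a log2 fold change of -0.96 (SE 0.17, adjusted p = 0.0174 by edgeR). Snrpd3, a core protein of the spliceosome (ENSMUSG00000020180, chromosome 10, 75517551 to 75537381), fell from 382 ± 59.0 to 247.6 ± 40.7 CPM (SD, n = 3 each). The AP-1 gene Jund fell from 492.1 ± 96.2 to 329.2 ± 33.8 CPM (SD, n = 3 each). Tsfm, a mitochondrial translation factor (log2 -0.78), Snhg15, a host of small nucleolar RNA (-0.69), and the glycosylation gene Mpdu1 (-0.65) fell too. So did Coq7 of ubiquinone synthesis (-0.64), Alyref of mRNA export (-0.63) and Frg1 (-0.58). Fth1, the ferritin heavy chain, rose from 370.4 ± 63.9 to 547.1 ± 75.5 CPM and the ubiquitin ligase gene Hectd3 from 19.9 ± 2.91 to 35.2 ± 3.73 CPM (SD, n = 3 each). The ribosomal protein gene Rps27 rose from 1138 ± 142.6 to 1564 ± 200 CPM (SD, n = 3 each). Bicd1, a dynein adaptor, had 27 counts in the 3 KO libraries and 3 in WT (ratio 9.16, 95% counting interval 2.82 to 47.2). Fth1 and Rps27 have processed pseudogenes, so the part of their reads assigned to a copy is uncertain.

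These 21 genes were called in Ebi3-KO against Ebi3-WT in CD8 among 12693 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The fit held all 18 libraries and shared 1 spread, which may be too narrow for CD8. CD8 pairs within a group differed by a chi-square per gene of 1.502 to 3.444, Treg pairs within a label by at most 1.41. With the Treg pairs that differed by less than the sampling noise summed into 1 sample each, only Bola1 was called, and with only the 6 CD8 libraries or only the 12 CD4 and CD8 libraries 0 genes were (1761 and 1689 unadjusted). An unadjusted p under 0.05 was reached by 2071 genes where 635 are expected by chance. In all 21 the 3 KO libraries lay entirely above or below the 3 WT libraries, and 4 of the 21 are predicted genes or have no symbol. Chance gives such separation for 10% of unselected genes, but the 21 were selected on the same libraries, so it adds no support. Hemoglobin was higher in the same KO libraries, at 1086, 994.5 and 1473 CPM against 635.3, 720.3 and 1069 in WT, a ratio of 1.47 between the means. With the hemoglobin level as a covariate 0 of the 21 genes passed edgeR's test, and the share of the log2 fold change that was left ran from 0.41 for Fth1 to 0.96 for Hectd3. The count was 5 with limma-voom, 135 with DESeq2, 35 with RLE scaling, 447 with no filter on low counts and 0 when a fold change over 1.5 was required. It was 8 without CD8 WT replicate 1, 0 without WT replicate 2, 646 without WT replicate 3, 48 without KO replicate 1, 61 without KO replicate 2 and 0 without KO replicate 3.

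By gene list, cell cycle and biosynthesis genes were lower and markers of other blood cells higher in the CD8 libraries labelled KO. Of 30 S phase genes 3 were higher and 27 lower (median log2 fold change -0.19, camera adjusted p = 0.00214), and of 30 G2 and M phase genes 4 were higher and 26 lower (-0.23, camera adjusted p = 0.00214). Both had an adjusted p = 0.56 with an estimated correlation. Sterol and fatty acid synthesis genes fell (7 higher, 24 lower, median -0.23, camera adjusted p = 0.00227; adjusted p = 0.56 with an estimated correlation). So did amino acid stress and unfolded protein genes (10 and 23, -0.18, camera adjusted p = 0.0026) and glycolysis and hypoxia genes (7 and 22, -0.18, camera adjusted p = 0.0313), both with an adjusted p = 0.56 with an estimated correlation. B cell markers rose (18 higher, 0 lower, median 0.47, camera adjusted p = 2.36e-07; adjusted p = 0.56 with an estimated correlation). Erythroid and platelet markers (7 and 0, 0.53, camera adjusted p = 0.000867) and myeloid and dendritic cell markers (8 and 2, 0.34, camera adjusted p = 0.0443) rose as well, both with an adjusted p = 0.56 with an estimated correlation. Thus 8 of 30 lists passed with the preset correlation, 0 with an estimated one and 0 by fry. Hemoglobin was 1.47 times the WT mean in the KO libraries that carried each of these shifts. Ribosomal protein genes took 8.91%, 8.92% and 9.53% of the counts in the same KO libraries against 8.66%, 7.77% and 8.36% in WT. With the hemoglobin level as a covariate 0 of the 8 lists passed, but the erythroid list holds genes of that covariate. The B cell genes Ighm and Ms4a1 followed hemoglobin closely in CD8 (n = 6, Pearson's r = 0.99 and 0.97). The loss of the erythroid and B cell lists is therefore not independent evidence. The medians were then 0 for S phase, 0.13 for G2 and M phase, 0.08 for sterol and 0.04 for both amino acid stress and glycolysis genes, and -0.08 for B cell, -0.13 for myeloid and 0.15 for erythroid markers. Without KO replicate 3 only S phase genes, B cell and erythroid markers passed, while 5 lists passed without WT replicate 1, with G2 and M phase, glycolysis and myeloid genes no longer among them. The myeloid markers were lost without KO replicate 1 as well (camera adjusted p = 0.0529), and 13 lists passed without WT replicate 3.

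No member of these 8 lists passed over all genes in CD8, and adjusted over the list alone 1 S phase gene was lower, Lig1, the replicative DNA ligase (log2 -0.47). Among G2 and M phase genes 3 were lower, Cenpe (-0.45), Plk1 (-0.47) and Mki67. Among sterol genes 4 were lower, among them Lss, the lanosterol synthase (-0.59), Mvd and Srebf2. Among amino acid stress genes 2 were lower, Ddit3 (-0.67) and Slc7a5, a large neutral amino acid transporter (-1.27, SE 0.27). Alas2, of heme synthesis (0.95), and the near-identical alpha globins Hba-a2 (0.74) and Hba-a1 (0.71) were the 3 erythroid genes higher, and 0 members of the B cell, myeloid or glycolysis lists passed. Other members with large differences, none past the threshold, were Mcm10 (-0.43), Tk1 (-0.40), Mcm7 (-0.40), Cenpf (-0.55) and Cks2 (0.49). In metabolism they were Ankrd37 (-0.96), Pfkm (-0.94), Gapdh (0.91), Aldoc (-0.56), Acat2 (-0.55), Mvk (-0.55), Idi1 (-0.52), Nupr1 (-0.92) and Vldlr (-0.82). Among markers of other cells they were Fcrla (0.64), Blk (0.57), Ighm (0.54), Cr2 (0.52), Csf1r (1.62), Zbtb46 (-1.02), S100a8 (0.72), S100a9 (0.62) and Car2 (0.53).

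The remaining lists missed the threshold in CD8, and Jund was the only member of them past it over all genes. Members named next are those that passed adjusted over the list alone. Interferon-stimulated genes (30 higher, 11 lower of 41) had a camera adjusted p = 0.0679, with Bst2 lower. T cell activation genes had 0.0679 with Slc7a5 lower, and CD4 lineage genes 0.101 with 1 higher and 2 lower (Ctla4, St8sia6, Tox). Inhibitory receptor genes had 0.104 with 3 lower (Ctla4, Tox, Nr4a3), Th1 genes 0.104, and p53 and apoptosis genes 0.104 with Bax lower. CD8 lineage genes had 0.14 with 3 lower (Cd8a, Klrk1, Ctsw) and chemokine receptor genes 0.14 with Ccr1 higher. Naive and memory genes gave 0.335, and IL-2 and STAT5 response, follicular helper and oxidative phosphorylation genes 0.415 each. Th2 genes gave 0.429, NF-kappaB response genes 0.451 with 3 lower (Nfkbib, Tnip1, Ltb), and cytotoxic genes 0.555 with 2 lower (Klrk1, Ctsw). Cytokine genes and Treg genes gave 0.635, the latter with 1 higher and 1 lower (Swap70, Socs2), and stress and immediate early genes 0.688 with Jun higher and Jund lower. Th17 genes and sex-linked genes gave 0.754, STAT3 and IL-27 response genes 0.818 with 2 higher and 2 lower (Il10, Bcl3, Il21r, Socs3), and EBI3 subunits and receptors 0.844. NK and innate-like T cell markers had only 3 tested members and no list test, with Tyrobp higher. Median, mean and test differed in sign for the EBI3 list (median -0.02, mean 0, test downward), the STAT3 list (-0.02, 0.03, downward) and the cytokine genes (0, 0.04, downward). Median and mean differed for the NK list (0.22, -0.1).

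**Figure D3:**
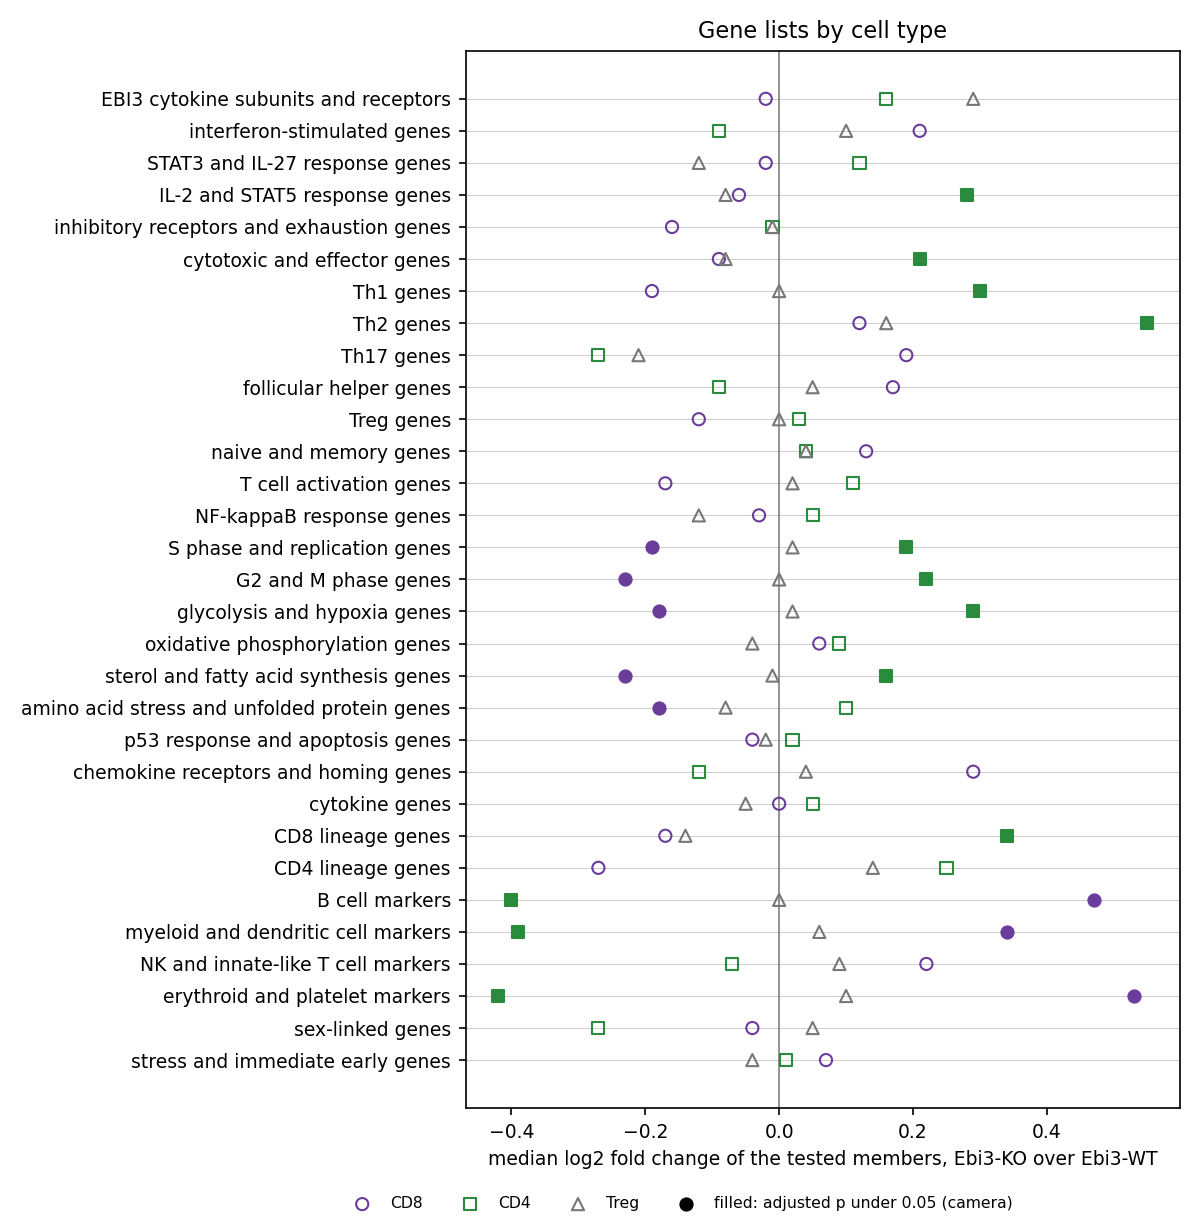
Median log2 fold change of KO against WT for each gene list in the libraries labelled CD8, CD4 and Treg, with filled points where camera with a preset correlation gave an adjusted p under 0.05. B cell markers lie at 0.47 in CD8 and -0.40 in CD4, and S phase genes at -0.19 in CD8 and 0.19 in CD4, while 0 lists pass in Treg.

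In CD4 cells, 0 genes passed the edgeR test over all genes between the libraries labelled KO and WT, and the lowest adjusted p was that of Ebi3 itself (0.127). An unadjusted p under 0.05 was reached by 929 genes where 635 are expected by chance. The count was 0 with limma-voom, 22 with no filter on low counts, 2 with only the 6 libraries compared (Slc7a5 and Akr1c18) and 1 with DESeq2, namely Slc7a5, whose log2 fold change was -1.56. It was 2 without CD4 WT replicate 1 (Eps8l1 and Ide), 2 without WT replicate 2 (Gm13935 and Ebi3) and 1 without KO replicate 2 (Gm7739). Simulated changes of 2-fold were recovered in 73.1% of genes in this comparison and changes of 1.5-fold in 29.9%. The simulation drew genes independently, with the same spread in all groups and without the real differences in hemoglobin between libraries. These shares may therefore not hold for the real CD4 libraries.

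By gene list, cell cycle, glycolysis, cytotoxic, Th1 and Th2 genes were higher in the CD4 libraries labelled KO and markers of other blood cells lower. All 30 S phase genes had positive fold changes (median log2 0.19, camera adjusted p = 2.67e-07; adjusted p = 0.372 with an estimated correlation). So had 26 of 30 G2 and M phase genes (0.22, camera adjusted p = 4.68e-05; adjusted p = 0.444 with an estimated correlation). Of 29 glycolysis and hypoxia genes 24 were higher (0.29, camera adjusted p = 1.61e-07; adjusted p = 0.317 with an estimated correlation). Sterol and fatty acid synthesis genes rose with 25 higher and 6 lower (0.16, camera adjusted p = 0.00851; adjusted p = 0.569 with an estimated correlation). IL-2 and STAT5 response genes (20 and 5, median 0.28, camera adjusted p = 0.000139) and CD8 lineage genes (12 and 1, 0.34, camera adjusted p = 0.000156) rose. Both had an adjusted p = 0.317 with an estimated correlation. Cytotoxic genes (16 and 10, 0.21, camera adjusted p = 0.0116) and Th1 genes (10 and 3, 0.30, camera adjusted p = 0.0143) rose, both with an adjusted p = 0.435 with an estimated correlation. B cell markers fell (0 higher, 18 lower, median -0.40, camera adjusted p = 1.15e-07; adjusted p = 0.435 with an estimated correlation). Myeloid and dendritic cell markers (2 and 8, -0.39, camera adjusted p = 0.00407) and erythroid and platelet markers (0 and 7, -0.42, camera adjusted p = 0.00737) fell, both with an adjusted p = 0.372 with an estimated correlation. Hemoglobin in the same KO libraries was 0.768 times the WT mean (755.8, 1008 and 888.6 against 1513, 879.6 and 1062 CPM), the opposite of CD8, and it moved with each of these lists. With the hemoglobin level as a covariate only the glycolysis list of these 11 passed (median 0.17, camera adjusted p = 0.00451), and it did not with an estimated correlation. The medians were 0.11 for S phase, 0.02 for G2 and M phase, 0.01 for sterol, -0.04 for B cell, -0.03 for myeloid and -0.07 for erythroid genes. The erythroid list holds genes of the covariate, and the B cell genes Ighm and Ms4a1 followed hemoglobin closely in CD4 (n = 6, Pearson's r = 0.99 and 1). The loss of the erythroid and B cell lists is therefore not independent evidence. CD4 WT replicate 1, with 1513 CPM of hemoglobin, differed from the other WT libraries by a chi-square per gene of 5.301 and 4.012, against 1.647 between those. Without it glycolysis genes (median 0.18, camera adjusted p = 0.00866) and B cell markers (-0.15, camera adjusted p = 0.0333) passed and the others of these lists did not, with S phase at 0.09 (camera adjusted p = 0.145), G2 and M phase at 0.09 (0.298), Th1 at 0.18 (0.523) and cytotoxic genes at 0.09 (0.379). Th1, sterol and erythroid genes were also lost without KO replicate 1, and Th1, cytotoxic and myeloid genes without KO replicate 3.

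The Th2 genes, which include the cytokines of type 2 immunity, rose in CD4 as well (9 higher and 2 lower of 11, median log2 0.55, camera adjusted p = 0.000613; adjusted p = 0.317 with an estimated correlation). Hemoglobin was 0.768 times the WT mean beside them too. The median was 0.36 with hemoglobin as a covariate (camera adjusted p = 0.00451) and 0.31 without CD4 WT replicate 1 (camera adjusted p = 0.00866). With the covariate and an estimated correlation the list did not pass. Adjusted over the list alone 6 were higher, the transcription factor gene Maf (1.06), Il24 (1.01), Ecm1 (0.88), Il5 (0.74), the chemokine receptor gene Ccr4 (0.60) and Il13 (0.55). Il10 was lower (-0.74), and 0 passed over all genes. Of the other 11 passing lists 0 members passed over the list alone or over all genes. Effector genes among them with large differences were Gzma (1.21), Crtam (0.86), the perforin gene Prf1 (0.77), Klrc1 (0.69), Il2 (0.72), Il12rb2 (0.50), Csf2 (0.46), Myc (-0.64) and Tnfsf10 (-0.90). Cell cycle genes were Chaf1a (0.39), Uhrf1 (0.38), Gins2 (0.35), Rrm2 (0.34), Cdc20 (0.44), Anln (0.37), Ccnf (0.36) and Nusap1 (0.35). Metabolic genes were Bnip3 (0.59), Slc16a3 (0.56), Pgk1 (0.56), Pfkl (0.45), Idi1 (-1.10), Elovl6 (0.44), Acat2 (0.39) and Sqle (0.34). Markers of other cells were Blnk (-0.61), Cd22 (-0.50), Cd79b (-0.50), Ighd (-0.48), Csf1r (-0.79), Zbtb46 (-0.75), Cd68 (-0.48), Cd74 (-0.45), Slc4a1 (-0.45), Alas2 (-0.43), Hba-a2 (-0.42) and Hbb-bt (-0.42). Near the floor, Il18rap had 2 counts in the 3 WT and 7 in the 3 KO libraries, Xcl1 0 and 5, and Gzmc 2 and 1. With Xcl1 at its bound and Gzmc left out, the list medians were 0.28 for IL-2 and STAT5 response genes, 0.34 for CD8 lineage genes and 0.26 for cytotoxic genes. In total 12 of 30 lists passed in CD4 with the preset correlation, and 0 with an estimated one or by fry.

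Among the remaining lists in CD4, oxidative phosphorylation genes and CD4 lineage genes had a camera adjusted p = 0.0919, and T cell activation genes 0.101 (Batf higher and Slc7a5 lower adjusted over the list alone). Interferon-stimulated genes, chemokine receptor genes and amino acid stress genes gave 0.158 (Slc7a5 and Dnajb9 lower in the last). STAT3 and IL-27 response genes gave 0.414 (Maf and Batf higher), sex-linked genes 0.468 and follicular helper genes 0.612. Treg genes gave 0.725 (Ebi3 lower), EBI3 subunits and receptors 0.736 (Ebi3 lower), and naive and memory genes 0.736. NF-kappaB genes and cytokine genes gave 0.802 (Il13 higher and Ebi3 lower in the latter) and inhibitory receptor genes 0.917. The p53, Th17 and stress genes gave 0.977 (Batf higher among Th17 and Ier3 among stress genes). Median, mean and test differed in sign for the EBI3 list (median 0.16, mean -0.36, test downward), Th17 genes (-0.27, -0.12, upward), Treg genes (0.03, -0.06, downward) and inhibitory receptor genes (-0.01, -0.01, upward). They differed too for p53 genes (0.02, -0.01, upward), cytokine genes (0.05, -0.03, upward) and stress genes (0.01, -0.03, upward), and median and mean for the untested NK markers (-0.07, 0.03).

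Among the libraries labelled Treg no gene and no list separated KO from WT by edgeR or camera. The edgeR test called 0 genes (lowest adjusted p = 0.999), limma-voom 0 and DESeq2 0. An unadjusted p under 0.05 was reached by 274 genes, fewer than the 635 expected by chance. The fit shared 1 spread over all groups. Within a label, Treg pairs had a chi-square per gene of at most 1.41. Within a group, CD4 and CD8 pairs had 1.502 to 5.301, at higher total counts. The shared spread may therefore be too wide for Treg, and the low count does not show that an effect is absent. Camera called 0 of 30 lists, with adjusted p between 0.21, for interferon-stimulated genes, and 0.97, for sterol genes, and 0.989 with an estimated correlation. Without Treg WT replicate 3 or KO replicate 1 it called 1 list, interferon-stimulated genes, upward (adjusted p = 0.00312 and 0.034). By fry, which asks only whether the members move to the same side on balance, the 8 EBI3 subunits and receptors were higher (6 higher, 2 lower, median log2 0.29, adjusted p = 0.0164). That test counted all 6 Treg libraries as separate samples, and it was not run with the pairs within sampling noise summed. Median, mean and test differed in sign for inhibitory receptor genes (-0.01, 0.04, upward), p53 genes (-0.02, 0.12, upward) and T cell activation genes (0.02, 0.04, downward). They differed too for glycolysis genes (0.02, 0.06, downward), cytokine genes (-0.05, -0.07, upward) and Treg genes (0, -0.04, upward). Hemoglobin lay between 1089 and 1210 CPM in all 6 Treg libraries, and a 2-fold change was recovered for 52.2% of simulated genes. The simulation drew independent libraries, whereas 4 of 9 real Treg pairs across the labels showed no difference beyond sampling noise. That share may therefore not hold for the real libraries.

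Averaged over the 3 cell types, 0 genes passed by edgeR (lowest adjusted p = 0.298), and 445 genes had an unadjusted p under 0.05 where 635 are expected. DESeq2, limma-voom and the mean over CD4 and CD8 only each called 1 gene, Slc7a5, a fit with no filter on low counts called 2 (Hjurp and Ide), and one with same-numbered libraries summed called 7. Leaving out CD8 WT replicate 2 gave 1 gene, Slc7a5, and leaving out CD4 WT replicate 1 gave 1 gene, the protease gene Ide. Ebi3 had a mean log2 fold change of -0.40 (SE 0.12, unadjusted p = 0.0025, adjusted p = 1 by edgeR). The Th2 genes were the only list of 30 to pass (10 higher and 1 lower of 11, median 0.11, camera adjusted p = 0.00581; adjusted p = 0.449 with an estimated correlation). They missed the threshold without Treg WT replicate 2 (adjusted p = 0.0943), where 0 lists passed. Interferon-stimulated genes passed beside them without CD8 WT replicate 3 or Treg WT replicate 3 (2 lists each), and sterol, amino acid stress, B cell and erythroid genes without CD4 WT replicate 1 (5 lists). Ecm1 (0.76) and Maf (0.48) were higher adjusted over the list alone and 0 passed over all genes, Il5 (0.64) and Il13 (0.18) among those that did not. In other lists Socs3 was higher and Ebi3, Ltb, Slc7a5 and Atf5 lower over the list alone. Median, mean and test differed in sign for EBI3 subunits (0.13, -0.05, upward), STAT3 genes (-0.02, 0, upward), chemokine receptor genes (0, -0.02, upward) and G2 and M phase genes (-0.01, 0.01, upward). They differed too for CD4 lineage genes (-0.01, 0.06, upward), sex-linked genes (-0.01, 0.02, downward) and T cell activation genes (0, 0.01, downward), and median and mean for the NK markers (-0.07, 0.02).

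Whether the effect of the genotype itself differed between cell types was tested directly. For CD4 minus CD8 0 genes passed by edgeR (lowest adjusted p = 0.065), 0 by limma-voom, 239 by DESeq2 and 602 by edgeR with no filter on low counts, and 2269 had an unadjusted p under 0.05. Ebi3 had a log2 difference of -0.97 (SE 0.27, unadjusted p = 0.00101, adjusted p = 0.0834 by edgeR). The count was 859 without CD8 WT replicate 3, 613 without CD4 WT replicate 2, 218 without CD4 KO replicate 2 and 150 without CD8 KO replicate 2. For Treg minus CD4 0 genes passed by edgeR (lowest adjusted p = 0.988), 0 by limma-voom and 0 by DESeq2, with 550 unadjusted and Ebi3 at 0.78. For Treg minus CD8 0 genes passed by edgeR (lowest adjusted p = 0.312), 0 by limma-voom and 0 by DESeq2, with 954 unadjusted and Ebi3 at -0.18. That count was 46 with no filter on low counts, 1 with only the 12 libraries compared (Ppp1r14b), 4 without CD8 WT replicate 3 (Fcgr2b, Bicd1 and Fth1 among them) and 1 without CD8 KO replicate 1 (Bst2).

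Among WT libraries, CD8 lineage genes and most cytotoxic genes were higher in CD8 cells, and the genes of the CD4 coreceptor and the CD40 ligand were higher in CD4 cells. All 13 tested CD8 lineage genes were higher in CD8 (13 over all genes and 13 adjusted over the list alone), among them Cd8a (log2 7.96), the perforin gene Prf1 (5.80) and Cd8b1 (4.90). Of 26 cytotoxic genes 19 were higher and 0 lower (20 and 0 adjusted over the list alone), among them Gzma (5.22), Crtam (4.28), Eomes (2.69) and Gzmb (2.67). Xcl1, a chemokine gene, was at least 116-fold higher in CD8, taking 3 counts over the group as the floor for CD4. Ifng, the interferon gamma gene, had a log2 fold change of 5.07. Cd40lg, the CD40 ligand gene, was at least 54.6-fold lower and Pdlim4 at least 4.96-fold lower in CD8. Cd4 was lower by a ratio of 334 (95% counting interval 92 to 2760), Ly6c1 by 192 (34.1 to 7650), and Tbc1d4 had a log2 fold change of -4.39. Within the EBI3 list (2 higher, 2 lower, and 2 and 3 adjusted over the list alone), Ebi3 was lower in CD8 than in CD4 (-0.65, adjusted p = 0.0313 by edgeR). Il12rb2, a subunit of the IL-12 receptor, was higher (1.31), and so was Il23a by a ratio of 24.4 (6.46 to 207).

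More genes were higher than lower in CD8 among IL-2 and STAT5 response genes, 13 against 0 over all genes and 16 against 1 adjusted over the list alone (Il18r1 3.26). The same held for Th1 genes (5 against 1 by both, Runx3 0.94), STAT3 and IL-27 genes (4 against 1 by both, Batf3 2.03) and glycolysis genes (4 against 0, and 7 against 0 over the list alone, Bnip3 1.32). Amino acid stress genes gave 4 against 0 (7 against 1, Asns 0.60). Of 41 interferon-stimulated genes 8 were lower in CD8 and 0 higher (16 and 0 over the list alone), among them Gbp5 (-1.27) and Ifi27l2a (-0.83). Follicular helper genes gave 1 higher and 4 lower of 10 (1 and 5, Slamf6 -0.80) and CD4 lineage genes 1 and 4 of 10 (1 and 7, Cd5 -0.61). Treg genes gave 5 higher and 5 lower (8 and 6, Ikzf2 1.89, Izumo1r -1.63), and naive and memory genes 4 and 6 (5 and 12, Ly6c2 3.03, Ccr7 -0.97). Inhibitory receptors gave 3 and 2 (4 and 4, Cd160 1.97), T cell activation genes 3 and 4 (5 and 7, Tnfrsf9 1.55), cytokines 4 and 5 (4 and 7) and Th2 genes 2 and 1 (2 and 2, Il24 3.55, Il5 -1.83). Chemokine receptors gave 1 and 2 (1 and 3, Gpr183 -0.98), stress genes 2 and 0 (3 and 2, Ier3 2.46) and S phase genes 1 and 0 (5 and 0, Ccne1 0.59). Sterol (Mvd 0.69) and p53 genes (Cdkn1a 0.95) gave 2 and 0 each, Th17 genes 2 and 1, NF-kappaB genes 1 and 1 (Traf1 0.94, Nfkbia -0.43) and NK markers 1 and 0 (Trdc 2.85). G2 and M phase, oxidative phosphorylation, B cell, myeloid, erythroid and sex-linked genes gave 0 and 0 by edgeR. The 18 B cell markers were all at lower values in CD8 (median -0.47), and hemoglobin was 635.3 to 1069 CPM in CD8 WT and 879.6 to 1513 CPM in CD4 WT.

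For CD8 against CD4 in Ebi3-WT the edgeR test called 682 of 12693 genes, 443 higher and 239 lower in CD8, and 633 of them had groups entirely apart. Chance gives this for 10% of unselected genes, but these were selected on the same libraries, so it adds no support. The count was 129 when a fold change over 1.5 was required, 226 with only the 6 libraries compared and 388 with only the 12 CD4 and CD8 libraries. It was 358 without CD8 WT replicate 1, 306 without WT replicate 2, 1265 without WT replicate 3 and 380 without CD4 WT replicate 3.

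Against CD4 cells of the same genotype, the WT libraries labelled Treg were low in cell cycle and biosynthesis genes. All 30 G2 and M phase genes were lower over all genes (30 adjusted over the list alone), among them Tpx2 (log2 -2.50), Top2a (-2.14), Mki67 (-1.98) and Birc5 (-1.57). Of 30 S phase genes 29 were lower and 1 higher by both adjustments (Hells -2.34, Rrm1 -1.99, Lig1 -1.83, Mcm3 -1.59). Of 31 sterol and fatty acid synthesis genes 26 were lower and 0 higher (27 and 0 over the list alone, Scd2 -2.07, Hmgcs1 -1.66). Of 29 glycolysis and hypoxia genes 14 were lower and 3 higher (14 and 4, Egln3 -4.06, Ldha -0.82). Naive and memory genes were mostly higher, 15 against 2 lower of 25 by both adjustments, with Txk (2.73), Cxcr4 (2.31) and Klf3 (1.67). Of the 26 tested Treg genes 10 were lower and 5 higher (11 and 5 over the list alone). The lower ones included Tnfrsf4 (-2.93), Ikzf4 (-2.10), Tnfrsf18 (-1.90) and Izumo1r (-1.88), all known for high expression in regulatory T cells.

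Of 13 CD8 lineage genes 7 were higher and 2 lower in the libraries labelled Treg (8 and 2 over the list alone), with Cd8a at 5.55, Prf1 at 3.40 and Cd8b1 at 3.01. Of 10 CD4 lineage genes 0 were higher and 4 lower (0 and 5 over the list alone), with Cd4 and Cd5 at -1.31 and Ctla4 at -1.34. Of 18 B cell markers 5 were higher and 0 lower by both adjustments (Fcer2a 1.96, Cd79a 1.57), and of 10 myeloid markers 4 and 0 by both (Csf1r 2.24, S100a9 1.82). Of 7 erythroid markers 1 was higher (Slc4a1), of 3 NK markers 1 (Trdc 2.77) and of 6 sex-linked genes 4 (Tsix 2.57, Eif2s3y 2.38). Hemoglobin was 1089 to 1210 CPM in all Treg libraries. Rises from 0 counts in CD4 WT, which have only a lower bound, included those of Greb1 (at least 55.5-fold, taking 3 counts over the group as the floor), Dlgap1 (at least 49.6-fold) and Ttc6 (at least 45-fold). S100b, which encodes a calcium-binding protein of glia (at least 44.3-fold), and the olfactory receptor gene Olfr1258 (at least 41.7-fold) were also among them. Falls to 0 counts in Treg WT, which also have only a bound, included those of Kif24 (at least 3.53-fold lower), the cytokine gene Csf2 (at least 2.69-fold lower) and Armcx4 (at least 2.52-fold lower). Lif was lower by a ratio of 31.3 (95% counting interval 5.41 to 1250) and Tnfsf11 by 23.7 (6.38 to 199).

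Of 8 EBI3 subunits and receptors 2 were higher and 2 lower in Treg by both adjustments, with Il6 at 3.19, Il12rb1 at -2.73 and Il23a higher by a ratio of 11.9 (2.65 to 109). Interferon-stimulated genes split into 9 higher and 8 lower by both (Ifi44 at least 14.5-fold higher, Psmb9 -1.89) and STAT3 genes into 4 and 4 by both (Maf 1.88, Junb -0.80). IL-2 and STAT5 genes gave 6 and 13 (6 and 14 over the list alone, Lta -2.93, Cish -2.39), inhibitory receptors 3 and 8 (3 and 9, Cd244a 3.47, Nr4a3 -2.02) and cytotoxic genes 9 and 8 (11 and 8, Ccl4 2.15, Serpinb6b -2.48). T helper lists gave 3 and 7 for Th1 (Tbx21 -2.36), 1 and 4 for Th2 (Gata3 -2.13, Il13 -2.54) and 2 and 0 for Th17 (Ccr6 2.59), each by both adjustments. Follicular helper genes gave 2 and 2 (2 and 3). T cell activation genes gave 6 and 10 (6 and 11, Nfkbid 1.80, Tfrc -1.34), NF-kappaB genes 11 and 5 (13 and 5, Nfkbiz 1.08) and oxidative phosphorylation genes 2 and 16 by both (Atp5c1 -0.96). Amino acid stress genes gave 9 and 14 (10 and 15, Atf5 2.45, Sdf2l1 -2.33) and p53 genes 5 and 9 (5 and 11, Bcl2l11 2.15). Chemokine receptors gave 10 and 3 (11 and 3, Gpr183 1.76), cytokines 6 and 12 (6 and 13) and stress genes 3 and 5 (3 and 3, Hspd1 -0.98).

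For Treg against CD4 in Ebi3-WT 5464 genes passed by edgeR, 3151 higher and 2313 lower in Treg, of which 5116 had groups entirely apart. Chance gives this for 10% of unselected genes, but these were selected on the same libraries, so it adds no support. With Treg WT replicates 1 and 2 summed into 1 sample the count was 5048, and it was 2498 when a fold change over 1.5 was required. The Treg libraries also differed in their make-up. They held 20034 to 20596 detected genes against 16193 to 17338 in the CD4 and CD8 libraries. The ribosomal RNA gene CT010467.1 took 3.83% to 4.5% of their counts against 1.71% to 2.34%.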

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

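The tests of 1 source of other-cell RNA, of Ebi3 loss as the cause of its spread, of Ebi3 counts per hemoglobin count, of a wrong label, the 3 tests on the Treg libraries and the list tests of the difference between CD4 and CD8 were chosen only after the result was seen. So were the interval on the depth correlation, its values within cell types and the check within cell types of Ebi3 per T cell receptor count.

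The effect of the Ebi3 label differed between CD4 and CD8 cells in 14 of 30 gene lists, by camera on the difference itself with a preset correlation. With an estimated correlation 0 of the 30 lists passed (lowest adjusted p = 0.336), and with hemoglobin as a covariate 0 passed. The erythroid list holds genes of that covariate, and B cell genes followed hemoglobin closely within cell types. The loss of the erythroid and B cell lists there is therefore not independent evidence. Cell cycle and metabolic genes lay higher in KO in CD4 and lower in CD8. The medians of the log2 difference were 0.39 for S phase (adjusted p = 4.07e-07), 0.47 for G2 and M phase (5.49e-06), 0.36 for glycolysis (5.49e-06), 0.37 for sterol synthesis (0.000268) and 0.31 for amino acid stress genes (0.00363). Of their members 29 of 30, 28 of 30, 27 of 29, 25 of 31 and 26 of 33 had positive differences. T cell lists followed, with 0.63 for CD8 lineage (adjusted p = 0.00125), 0.30 for IL-2 and STAT5 response (0.00496), 0.38 for Th1 (0.0101), 0.17 for T cell activation (0.0246) and 0.49 for CD4 lineage genes (0.0246). Markers of other blood cells went the other way, with -0.89 for B cell (adjusted p = 8e-11), -0.89 for erythroid (9.33e-05) and -0.71 for myeloid markers (0.00188). The 18 B cell and 7 erythroid members were all negative. Interferon-stimulated genes stood at -0.21 (adjusted p = 0.0337), with 0.21 in CD8 and -0.09 in CD4. The lists set before the data were examined hold 18 B cell and 16 erythroid markers, of which 0 stand in another list.

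Hemoglobin ranged from 635.3 to 1513 CPM and Ighm from 1470 to 3390 CPM over the 12 CD4 and CD8 libraries, although sorting for T cells should remove red cell precursors and B cells. The factor between single libraries of 1 group reached 1.72. The ratio of group means was 1.47 for KO to WT in CD8 and 1.3 for WT to KO in CD4, in opposite directions. Ratios of single libraries and of means are unlike measures, so their sizes do not weigh against an effect of the label. The spread within a group, where the label is the same, argues against loss of Ebi3 as the only cause. Ighm per hemoglobin count varied by only 4.09% (coefficient of variation) where hemoglobin itself varied by 26.8%, and Ms4a1 per hemoglobin by 5.64%, so RNA of other spleen cells that entered from a single source in varying amounts is a candidate explanation. Depth stays open, because its correlations with hemoglobin cannot decide it. Hemoglobin in CPM has the total count as its divisor, so a negative correlation can follow from the ratio alone. In CD4, hemoglobin counts ran only from 1705 to 2056, while total counts ran from 1358671 to 2255950. Over the 12 libraries total count and hemoglobin in CPM gave Spearman's rho = -0.44 (permutation p = 0.155). Its interval of -0.81 to 0.178 crosses the bound of -0.6 set before. Pearson's r was -0.54 (permutation p = 0.0723), or 0.08 without the 2 farthest libraries. Within CD4 rho was -0.94 (n = 6, exact permutation p = 0.0167, adjusted p = 0.0501 over 3 relations) and r -0.98 (exact permutation p = 0.00278, adjusted p = 0.00834), or -0.93 without the 2 farthest, and within CD8 rho was 0.2 (exact permutation p and adjusted p = 0.714) and r 0.43 (exact permutation p and adjusted p = 0.383).

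Ebi3 was counted in all libraries labelled KO. Per hemoglobin count the 6 CD4 and CD8 KO libraries did not differ by more than counting error (chi-square p = 0.96), but neither did the 6 WT libraries (0.0755), nor the KO libraries per total count (0.11). Per T cell receptor and CD3 count the KO libraries differed by more than counting error (1.1e-06, and 0.000734 with 1 level per cell type), which ordinary variation between samples could give as well. Ebi3 transcripts that came in with RNA of other cells and a transcript of the changed allele made in the T cells therefore cannot be told apart, because the counts are few and counting error is the only yardstick. CD8 WT replicate 3 lay closer to the CD8 libraries labelled KO (mean chi-square per gene 2.11) than to the other CD8 WT libraries (3.36), but its hemoglobin (1069 CPM) lies in the range of those KO libraries (994.5 to 1473 CPM), and a wrong label and this makeup cannot be told apart.

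The libraries labelled Treg held 0 or 1 count of Foxp3 and both coreceptor genes. Whether YFP/cre in Foxp3 changes the 3' tag of that gene was not tested, so the counts of Foxp3 alone do not decide on the label. Loss of Foxp3 reads in counting, to the gene on the other strand, stays open: of 811 protein-coding genes with at least 0.8 of the 3' end covered 57.2% were detected against 42.7% of 21163 others, but Foxp3, with 0.32 covered, is not among the 811. A mixture of the cells of the CD4 and CD8 libraries would keep shared activation genes at the summed coreceptor share of 59.6%, but Mki67 stood at 29.6%, Top2a at 24.9%, Il2ra at 22.1% and Tnfrsf4 at 17.4% of the lower of the CD4 and CD8 levels. Equal RNA of 1 pool in all 6 libraries, with no variation added in preparation, would leave all 15 pairs within sampling noise, as 6 pairs were. WT replicate 1 and KO replicate 2 differed by a chi-square per gene of 1.612 (p = 1.11e-272). Sampling noise was the only yardstick, so a difference beyond it cannot exclude 1 pool prepared as separate libraries. Pairs across the genotype labels differed on average by 1.14 and pairs within a label by 1.17 (highest 1.41), and a genotype with little effect in these cells was not tested apart.

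The 6 libraries of a simple comparison allow only 10 splits, too few for a share under 0.05. The labelled split called 21 genes in CD8 (highest other 0), 0 in CD4 (highest other 1), 0 in Treg (highest other 0), 682 for CD8 against CD4 (highest other 325) and 5464 for Treg against CD4 (highest other 0). As many genes as the labelled split came from 1 of 10 splits in CD8, CD8 against CD4 and Treg against CD4, and from 10 of 10 in CD4 and Treg, as a count of 0 must. The split with 325 genes set CD8 WT replicates 1 and 2 and CD4 WT replicate 2 against the others, the 3 WT libraries of lowest hemoglobin. For the average and the differences between cell types the labels gave 0 genes, which all 100 splits match whatever they call, so that the comparison says nothing about chance. The highest other split called 192 genes for the average, 1333 for CD4 minus CD8, 2 for Treg minus CD8 and 0 for Treg minus CD4. The splits with 192 and 1333 genes parted the libraries by hemoglobin (log2 differences of 0.64 in CD8 and 0.49 in CD4 in the first, -0.64 and 0.49 in the second, against 0.57 and -0.35 for the labels), which points to a structure of the samples other than the labels.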

How the results depend on the processing

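The hemoglobin covariate, the fit of the 12 CD4 and CD8 libraries, the mean over CD4 and CD8 only, the summing of Treg libraries within sampling noise and the list tests without single libraries were tests chosen only after the result was seen. Of counts of genes and lists 163 stayed within 1.5 times under an alternative and 71 did not, and of single values 4080 were the same, 333 lost and 42 gained the threshold and 12 changed sign. For Ebi3-KO against Ebi3-WT in CD8 the 21 genes became 35 with RLE scaling, 447 with no filter on low counts, 135 with DESeq2, 5 with limma-voom, 6 with the covariate, 1 with Treg libraries within sampling noise summed (Bola1), and 0 when a fold over 1.5 was required (194 unadjusted). With only the 6 libraries compared or only the 12 CD4 and CD8 libraries edgeR called 0 (1761 and 1689 unadjusted), and without single libraries 0 (WT replicate 2 or KO replicate 3) to 646 (WT replicate 3). For Ebi3-KO against Ebi3-WT in CD4 the 0 genes became 22 with no filter, 1 with DESeq2 (Slc7a5), 2 with only the 6 libraries (Slc7a5, Akr1c18), 2 with the covariate (Hjurp, Ide) and 0 to 2 without single libraries. For Ebi3-KO against Ebi3-WT averaged over the 3 cell types the 0 became 2 with no filter (Hjurp, Ide), 1 with DESeq2, limma-voom or CD4 and CD8 only (Slc7a5 each time), 7 with same-numbered libraries summed (Gapdh, Slc7a5, Rpl29, Akr1c18, Gm7739, Rps2, Ide) and 0 to 1 without single libraries. For the difference of the Ebi3-KO effect, CD4 minus CD8, the 0 became 602 with no filter, 239 with DESeq2 and 0 to 859 without single libraries (859 without CD8 WT replicate 3). For the difference of the Ebi3-KO effect, Treg minus CD8, the 0 became 46 with no filter, 1 with only the 12 libraries compared (Ppp1r14b) and 0 to 4 without single libraries. Ebi3-KO against Ebi3-WT in Treg and the difference of the Ebi3-KO effect, Treg minus CD4, stayed at 0 genes under all alternatives run (274 and 550 unadjusted by edgeR). For CD8 against CD4 in Ebi3-WT the 682 genes became 129 when a fold over 1.5 was required, 226 with only the 6 libraries, 388 with the 12, and 306 (without CD8 WT replicate 2) to 1265 (without CD8 WT replicate 3) without single libraries, and other settings gave 458 to 963. For Treg against CD4 in Ebi3-WT the 5464 became 2498 when a fold over 1.5 was required, and other settings gave 3978 to 7894. The required fold asks for more by construction; for the other moved counts the cause was not tested.

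Of gene lists, 0 passed with an estimated correlation or by fry in CD8, CD4 and the mean (8, 12 and 1 with the preset one), and fry called 1 in Treg (EBI3 subunits and receptors) where camera called 0. With the covariate 1 list passed in CD8 (oxidative phosphorylation), 2 in CD4 (Th2, glycolysis) and 4 in the mean (Th2, G2 and M phase, glycolysis, B cell markers), and 0 in each with the covariate and an estimated correlation. Without single libraries 3 (KO replicate 3) to 13 (WT replicate 3) lists passed in CD8, 3 (WT replicate 1) to 16 (WT replicate 2) in CD4, 0 to 1 in Treg and 0 (Treg WT replicate 2) to 5 (CD4 WT replicate 1) in the mean, and the cause was not tested.

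The replicate number used as a block left 12 genes in Ebi3-KO against Ebi3-WT in CD8, all among the 21, and 9 lists there (interferon-stimulated genes added), and it moved no other count of genes or lists by over 1.5 times. Correlations of same-numbered deviations ran from -0.34 to 0.31 and not every pair passed 0.1, so they gave no clear pairing of the samples. With so few libraries per group they cannot exclude shared animals or cultures. Every library correlated best with its own number in 1 of 9 pairs of groups, CD4 with Treg in KO.

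Among single genes, signs turned for values that had not passed, and the cause was not tested. Medians of lists that had passed in CD8 also turned sign with the covariate, such as G2 and M phase genes (-0.23 to 0.13) and B cell markers (0.47 to -0.08). Ebi3 in CD8 was 0.01 without WT replicate 3 or KO replicate 1 and 0.10 without KO replicate 2, in a range from -0.16 to 0.10. In CD4, Slc4a1 was 0.46 without WT replicate 1 (range -1.09 to 0.46), and Csf2 -0.10 (to 0.87) and Klrc1 -0.16 (to 1.15) without KO replicate 3. With the covariate in CD8 Idi1 was 0.19, Nupr1 0.18, Vldlr 0.22, Blk -0.11 and S100a9 -0.33, and Ebi3 for Treg minus CD8 was 0.14. RLE scaling and DESeq2 moved the median of all genes by at most 0.035 (log2). Depth limits genes near 3 counts, and whether it is what limits Foxp3 was not tested. Of 1.5-fold changes 14.9% to 29.9% were recovered in simulated KO against WT comparisons within a cell type, and whether depth, spread or the number of libraries limits this was not tested.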

Other observations

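Of the tests below, only the count of genes near Ebi3 and the comparison of library pairs were set before the data were examined, and the others and the genes named were chosen only after the result was seen. The 6 libraries labelled Treg held transcripts of many genes that T cells are not known to use. Of 1093 olfactory receptor genes 201 to 222 were detected in each Treg library, against 7 to 21 in each CD4 or CD8 library, although Treg libraries had fewer total counts. A set of 1023 genes had 0 counts in all 12 CD4 and CD8 libraries and at least 10 summed counts in the Treg libraries, 389 of them protein-coding and 58 olfactory receptor genes. The reverse held for 233 genes. S100b, a calcium-binding protein of glia, had 129 counts over the 6 Treg libraries, Prune2 89, the homeobox gene Otx2 72, the dopamine receptor gene Drd1 63 and Aqp7 63, at similar counts in each library and at 0 in the 12 others. Mitochondrial genes took 6.77% to 7.59% of counts in Treg and 6.1% to 6.96% in the others. No explanation of these counts was tested.

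Transcripts of both sexes were counted in every library. Ddx3y, from the Y chromosome, stood at 10.2 to 31.3 CPM in the CD4 and CD8 libraries and 32.8 to 73.7 CPM in the Treg libraries, and Xist, from the inactive X, at 444 to 772 and 621 to 880 CPM. Within a cell type (n = 6, 12 relations, exact permutation tests) Ddx3y followed hemoglobin, with r = 0.96 in CD8 (p = 0.00833, adjusted p = 0.0143; 0.96 without the 2 farthest libraries) and 0.97 in CD4 (p = 0.00417, adjusted p = 0.00834; 0.7 without them). Spearman's rho was 0.89 (exact permutation p = 0.0333, adjusted p = 0.05) and 0.94 (exact permutation p = 0.0167, adjusted p = 0.0334). Xist ran the other way, with r = -0.98 in CD8 (exact permutation p = 0.00278, adjusted p = 0.00834; -0.92 without the 2 farthest) and -0.87 in CD4 (exact permutation p = 0.0236, adjusted p = 0.0315). Its rho was -0.94 (exact permutation p = 0.0167, adjusted p = 0.0334) and -0.89 (exact permutation p = 0.0333, adjusted p = 0.05), and in CD4 r was -0.38 without the 2 farthest, so that it rests on those. Slc7a5 did not follow hemoglobin, with r = -0.49 in CD8 (exact permutation p = 0.308, adjusted p = 0.336) and 0.23 in CD4 (exact permutation p and adjusted p = 0.756). Spearman's rho was -0.6 (exact permutation p = 0.242, adjusted p = 0.29) and 0.26 (exact permutation p and adjusted p = 0.658), and r without the 2 farthest 0.05 and 0.26.

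The effects of the label in CD8 and CD4, which share no libraries, were weakly opposed over all genes, with a correlation of log2 fold changes of -0.13 across genes, or -0.37 at a mean log2 CPM of 4 or more. Of 258 genes with an unadjusted p under 0.05 in both, where 152 are expected for independent lists, 32 had the same direction. Across 8252 genes with a mean log2 CPM of 4 or more, which are not independent replicates, the log2 fold changes correlated with the fitted slope on hemoglobin with r = 0.58 in CD8, -0.58 in CD4 and 0.05 in Treg. That slope was called for 1162 genes upward and 872 downward by edgeR, and it was fitted within groups on the same libraries, so that the correlations are not from independent samples.

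With the hemoglobin covariate 6 genes were called in Ebi3-KO against Ebi3-WT in CD8. Ltb, which encodes lymphotoxin beta, was lower (log2 -0.98), and Smim26 (1.33), Nob1 (1.21), Igf2r (0.79), Uqcrfs1 of respiratory complex III (0.55) and the kinase gene Pim1 (0.47) were higher. Hjurp, the chaperone of the centromeric histone (-0.70, adjusted p = 0.00235 by edgeR), and Ide, the insulin-degrading enzyme (-0.75, adjusted p = 0.00566 by edgeR), were lower in CD4. Ebi3 then stood at -0.37 in CD8, -0.76 in CD4 (adjusted p = 0.117 by edgeR) and -0.23 in Treg. Of the Th2 genes in CD4, Maf (1.07) and Il4ra (0.31) passed adjusted over the list alone with the covariate, each at 0.0181, and Il24 (0.79), Ecm1 (0.83) and Il13 (0.36) did not, each at 0.0651. Nor did Ccr4 (0.36, at 0.108), Il5 (0.54, at 0.241) or Il10 (-0.43, at 0.255). The fitted slope on hemoglobin was 0.06 for Maf and -0.61 for Il13, and the Th2 list was among the 2 lists that passed camera in CD4 with the covariate and the preset correlation (adjusted p = 0.00451; adjusted p = 0.471 with an estimated correlation).

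Within 10 Mb of Ebi3 on chromosome 17, where sequence of a donor strain often stays linked to a changed allele, 0 of 114 tested genes, Ebi3 itself included, were called. For the average 8.77% of these had an unadjusted p under 0.05 against 3.46% of other genes (Fisher's exact p = 0.0067, adjusted p = 0.0268 over 4 comparisons). The shares were 12.3% against 7.27% in CD4 (Fisher's exact p = 0.047, adjusted p = 0.094), 20.2% against 16.3% in CD8 (exact p = 0.253, adjusted p = 0.253) and 4.39% against 2.14% in Treg (exact p = 0.101, adjusted p = 0.135).

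Treg WT replicate 3 and Treg KO replicate 2, of different labels, differed least of all pairs (chi-square per gene 0.869, p = 1 over 9623 genes). They shared the higher Cd4 levels (60.2 and 68 CPM), the lower Cd8a levels (29.6 and 24.9 CPM) and the higher Ddx3y levels (65.9 and 73.7 CPM) among the 6 Treg libraries.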
